A study of Mus musculus with 20 samples.

How the data were processed

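Hepa1-6 cells, a mouse hepatoma line, were grown in flasks until confluent and then followed for 96 h. Medium was exchanged in every flask at the start and after 24, 48 and 72 h. Control flasks held 4 mM glutamine throughout, whereas experimental flasks were moved between 0 and 4 mM glutamine at these exchanges, per the labels. RNA sampled at regular intervals was hybridised to spotted DNA arrays, with control RNA labelled with Cy3 and experimental RNA with Cy5. The series holds 20 arrays of 11 numbered time points. Time points 1 to 4 and 6 to 10 had 2 arrays each, the second marked with an r in its title, and time points 5 and 11 had 1. The labels give neither the hour of a time point, nor the glutamine level of the flask sampled, nor whether r marks a repeat hybridisation or another flask. No glutamine level was therefore assigned to any time point, and p-values may measure technical spread only.

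The deposited values were taken as log2 ratios of both channels of an array, 1 column per array. Neither the scale, the direction nor the normalization of these values is given in the sources used here. Base 2 was inferred from the second array of time point 10, where repeated values would be ratios of small whole numbers in that base. The highest repeated value, 16.92 on 111 spots, is too large to be such a ratio. This reading rests on 1 array, stayed open in the test given later, and was taken to hold for the other arrays, so the base is an assumption. The direction is likely experimental over control, because the labels list the experimental RNA as channel 1 and the control RNA as channel 2, and all arrays share this layout. For 1 array of time point 4 the label of channel 2 names cells without glutamine, which was treated as a slip, and time point 4 was left out in an alternative. Because no array had swapped dyes, a bias of a gene for a dye and a constant difference between the flasks cannot be told apart. Spot intensities were not used here, so that background correction and intensity-dependent normalization could be neither checked nor redone. Array medians lay between 0.05 and 0.435, all above 0, so the deposited values were not centred on the median of the spots with a value. Another normalization before deposit is not excluded. Each array was centred on its median for this work. All values below are therefore relative to the median probe of the array.

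Of 17280 probes, 4769 had no value on any array. An array gave between 4269 and 8269 values, which is 24.7% to 47.9% of its probes. The rule by which spots were left blank is not given in the sources used here. The platform annotation listed 14719 probes, of which 14718 had 1 gene symbol and 1 had several, and 2562 probes had no symbol that could be used. A reference gene table matched 14445 of the listed probes, and no symbol changed. Probes of 1 symbol were averaged, and probes without a symbol were kept under their number as unnamed here. The number of arrays limits the precision of all values.

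Tests were run in R 4.3.3 with limma 3.58.1. For the mean difference over time points, the arrays of a time point were averaged, and limma tested the mean of the 11 time points against 0 in genes with a value at 9 or more. For differences among time points and for single time points, limma was fitted to all 20 arrays with a mean per time point, in genes with a value on 16 or more arrays, and the spread came from the 9 time points with 2 arrays. For a periodic component, limma tested sine and cosine terms with a period of 5 steps on the time-point means. Benjamini-Hochberg adjusted p under 0.05 counted as called. Similarity between profiles was tested with 100000 permutations of the time-point order. Gene lists with 5 or more measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation. They were also tested with fry and with an exact sign-flip test over time points. The limma test of the mean and the sign-flip test treat time points as independent. Neighbouring time points were more alike than others, as given below, so these p-values may be too small. The lists covered metabolism, stress responses, growth, secreted liver proteins and markers of liver cell types, and 39 lists were fixed. The test designs, the lists, the first alternatives and the rule for naming genes were set before the data were examined.

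The rule names the 10 highest and 10 lowest called genes that had 1 sign at 9 or more time points, the 10 genes with the smallest F-test p, and the 2 highest and 2 lowest called genes of each time point with 2 arrays. It also names the 5 genes with the smallest p of the periodic fit if none was called, up to 4 called members of a list (otherwise the 2 with the largest mean), and Asns, Glul, Ddit3, Slc38a2 and Slc1a5. A further gene of the rule is not reported here.

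Inspection of the arrays led to settings chosen after seeing the data. The second arrays of time points 6 and 10 did not correlate with the other 18 arrays, but correlated with each other at 0.397. On the first arrays of time points 5 and 6 the spots at the first 3 of every 20 probe numbers were raised. A reduced set left out the second arrays of time points 6 and 10. It also blanked the raised positions on the first arrays of time points 5 and 6. Further settings centred the reduced set within blocks of 540 probe numbers, or left out time points 5 and 6 and the second array of time point 10. A period of 6.5 steps was also added. The first alternatives covered centring, scaling, the number of values required, single probes, the sign and the use of arrays titled with r, a block for them, single time points or arrays left out, robust variance estimation, the threshold and the periods 4, 5.5 and 6.

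The limma tests and camera were tested on simulated data with the blanks of the real arrays and spreads drawn from them, in which 200 genes were changed. The largest spreads over time points were left out of the draw, so the shares found may be too high. For the mean difference over 4752 genes, 96% of genes shifted by 0.5 and 100% of those shifted by 1 were found, with 20 false calls. Among 3744 genes in the array fit, the F test found 0% of genes changed by 1 at 1 time point and 80% of those changed by 1 at 4 time points. The single time-point test found 69% of changes of 1 and 7% of changes of 0.5. The median simulated SD between arrays was 0.22. Whether the simulation held pairs of arrays that did not correlate, as at time point 10, was not checked. On the real arrays the F test called 262 genes, and 1055 without the second array of time point 10. The shares for the F test and for single time points may therefore be too high for all arrays. The periodic fit found 99% of amplitudes of 1 and 67% of amplitudes of 0.5, over 4752 genes. All 5 shifted lists were found by camera. Genes were simulated as independent, so this does not show how camera behaves where list members vary together. On all arrays the estimated correlation was 0.122 for glycolysis and 0.158 for ribosomal proteins, above the preset 0.01. The permutation tests and the other list tests were not checked in this way.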

Results

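The study asked how the transcripts of Hepa1-6 mouse hepatoma cells respond when glutamine, the amino acid that many cultured cells use as a carbon and nitrogen source, is repeatedly withdrawn and returned. Each array compared RNA of flasks with varied glutamine with RNA of flasks kept at 4 mM, and 20 arrays covered 11 time points. A positive log2 ratio likely means a higher level in the glutamine-varied flasks, since the labels list that RNA first. All ratios are relative to the median probe of the array.

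The arrays of 1 time point resembled each other, with a correlation across probes between 0.518 and 0.691 at 7 time points, but they did not at time points 6 (r = 0.0539) and 10 (r = -0.0168). Of the arrays of the 7 time points, only both of time point 7 and the first of time point 9 correlated best with their partner. The others correlated best with an array of another time point. The second array of time point 1, for example, reached 0.683 with the second of time point 4, against 0.520 with its partner. Part of the resemblance was therefore common to several time points. It does not by itself measure how well a single time point was reproduced. Genes are not independent replicates, so these values describe the arrays only. The spots that gave a value on the second array of time point 6 were unrelated to those of the others: the correlation of spots that gave a value was 0.00704, against 0.702 to 0.873 on the other 19 arrays. On the second array of time point 10, 111 spots had the value 16.92 and 331 had the value 0.31 as deposited, and 16.92 became 16.87 on centring. The arrays of time points 5 and 6 had another peculiarity. Spots at the first of every 20 probe numbers had a median of 2.72 (time point 5) and 1.28 (the first array of time point 6), against -0.10 to 0.08 on the other 18 arrays. Results are therefore given for all 20 arrays, as designed, and beside them for the reduced set of 18 arrays without these spots.

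**Figure D1:**
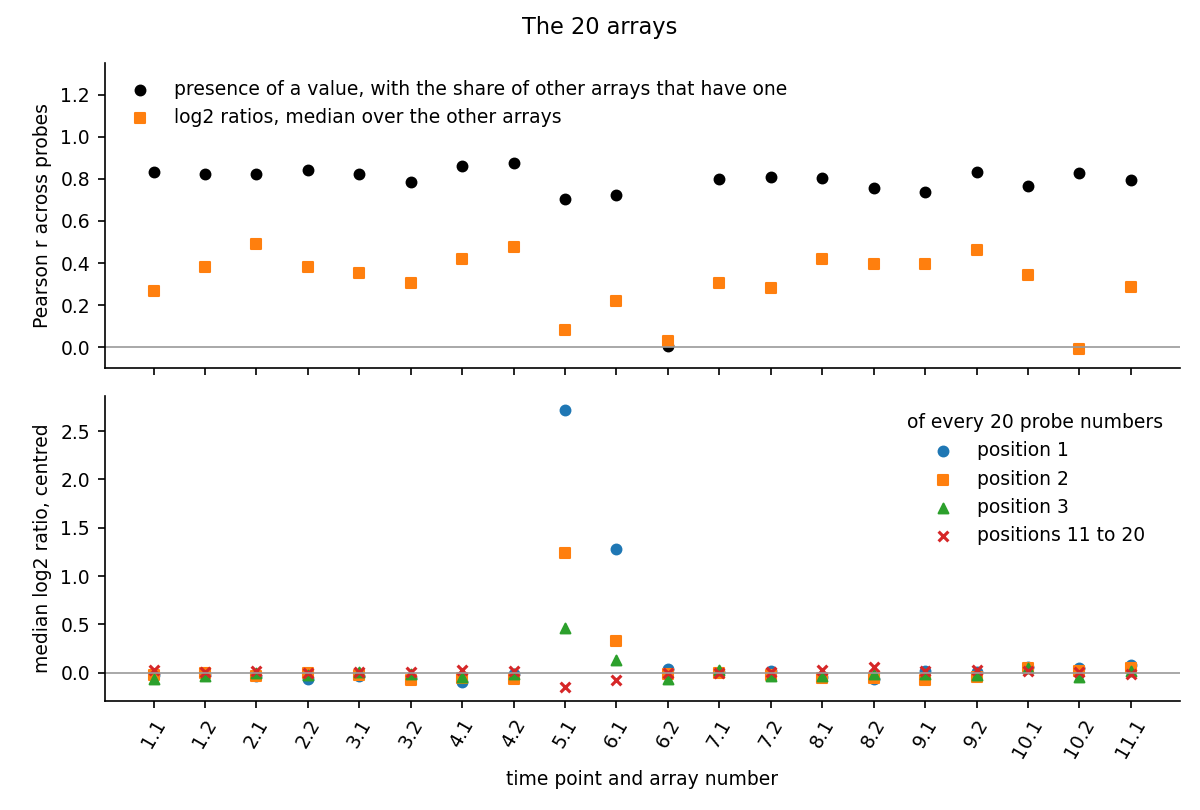
Quality of the 20 arrays, labelled by time point and array number. The upper panel shows, per array, the Pearson correlation of the presence of a value with the share of other arrays that gave one (circles) and the median correlation of its log2 ratios with those of the other arrays (squares); the lower panel shows the median centred log2 ratio of spots at positions 1, 2, 3 and 11 to 20 of every 20 probe numbers. The second array of time point 6 lies at 0.00704 for the presence of values, and position 1 lies at 2.72 at time point 5.

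The mean difference over all time points asked which transcripts stayed higher or lower in flasks with varied glutamine whatever the sampling. No array had swapped dyes, so a constant dye bias of a gene would give the same pattern. The genes and lists given for this mean are therefore not shown to respond to glutamine. Among the lowest were Notch3, a receptor of the Notch family, at a mean log2 ratio of -0.84 ± 0.32 (SD, n = 11 time points), and Pacc1, a proton-activated chloride channel, at -0.77 ± 0.39 (SD, n = 11). Cit, a kinase of cell division, lay at -0.75 ± 0.30 (SD, n = 10) and Fam162a, a hypoxia-inducible mitochondrial protein, at -0.75 ± 0.35 (SD, n = 9). Each of these was negative at every time point measured. Higher genes included Aif1, a calcium-binding protein best known from macrophages, at 0.69 ± 0.34 (SD, n = 11), the transcription factor Nfia at 0.67 ± 0.25 (SD, n = 11), and the unnamed probe 9434 at 0.61 ± 0.22 (SD, n = 11), all positive at 11 time points.

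Of 4752 genes tested with limma, 646 were higher and 430 lower at an adjusted p under 0.05. Their median sizes were 0.27 and 0.30 on the log2 scale. Of 596 genes with a value on every array, 187 were higher and 34 lower. Of 6460 genes with a value at 6 or more time points, 597 were higher and 605 lower. The balance of directions thus changed with how often a spot gave a value, and the cause was not tested. The adjusted p was 0.000287 for Notch3, Nfia and probe 9434, 0.000759 for Aif1, 0.000764 for Pacc1, 0.000474 for Cit and 0.00117 for Fam162a. The remaining lowest genes were Gpr153, Ssbp2 and the unnamed probes 17198, 17156, 17148 and 14984, with means between -0.68 and -0.76. Probes 17148, 17156 and 17198 have close numbers in the same block of 540 probe numbers. Such blocks held 0.19% to 29.0% of the variance of an array (median 12.5%), so an effect of place was not excluded. The remaining highest were 1810009A15Rik (0.78 ± 0.90, SD), the integrin subunit Itga4 (0.75 ± 0.94), the stress-inducible Gadd45b (0.65 ± 0.59), the macrophage growth factor Csf1 (0.60 ± 0.71), the transcriptional co-regulator Cited1 (0.60 ± 0.53), Kdm5d (0.59 ± 0.54) and the endoplasmic reticulum stress sensor Ern2 (0.59 ± 0.57), each over 11 time points. These large SDs came with high values at time point 5, such as 3.16 for Itga4 and 2.90 for 1810009A15Rik, and all but Ern2 have a spot at the raised positions. Without those spots and arrays, Itga4 had a mean of 0.38 ± 0.32 (SD, n = 9), 1810009A15Rik 0.53 ± 0.55, Gadd45b 0.48 ± 0.18, Csf1 0.33 ± 0.22, Cited1 0.44 ± 0.18 and Kdm5d 0.38 ± 0.13, all with n = 9 and still past the limma test.

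**Figure D2:**
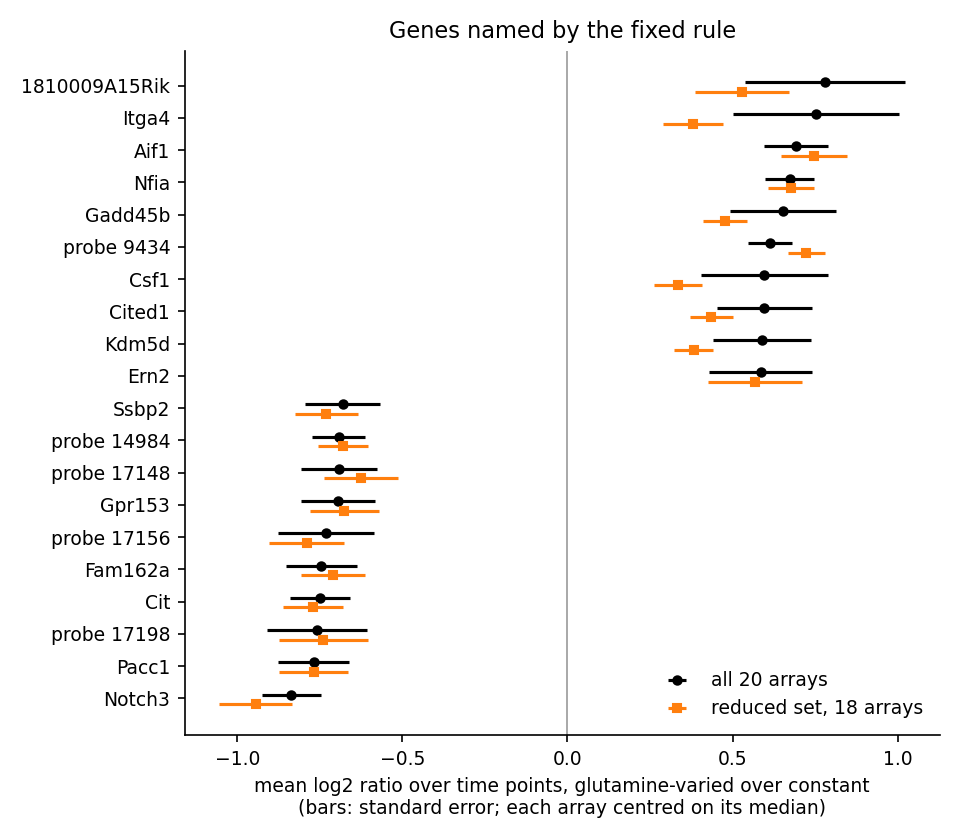
Mean log2 ratio over time points (x axis, glutamine-varied over constant glutamine) of the 20 genes that the rule named. Circles give all 20 arrays and squares the reduced set of 18 arrays, with bars for the standard error over time points; Notch3 lies at -0.84 and -0.94, and Itga4 at 0.75 and 0.38.

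The reduced set had 982 of 4251 genes higher and 548 lower. There 981 of the 1076 genes called on all arrays were called again, all with the same sign. Here the named genes were led by Aif1 (0.75 ± 0.40, SD, n = 11) and followed by probe 9434, Nfia, the calcium-binding protein S100b (0.65 ± 0.19, n = 11), Zfp934 (0.59), the ubiquitin ligase Marchf3 (0.57 ± 0.10, n = 11), Ern2, the kinetochore protein Ndc80 (0.57), Mfge8 (0.56) and 6530415H11Rik (0.55). On the lower side stood Notch3 (-0.94 ± 0.41, n = 9), Pfkl, the liver form of phosphofructokinase (-0.81 ± 0.44, n = 10), Acrbp (-0.81), probe 17156, Cit, Pacc1, probe 17198, Ssbp2, Ccdc125 (-0.72) and Fam162a, all with limma adjusted p of 0.000620 or less. Without centring, 2849 genes were higher and 46 lower, because the array medians themselves lie above 0. These calls therefore hold only relative to the median probe. With the sign of the arrays titled r turned, none of the 4752 genes was called.

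Genes of glycolysis, which breaks glucose down to pyruvate and lactate, lay below the median, and 5 of 10 measured members fell and 1 rose on all arrays (6 and 1 adjusted over the list alone). The called members were led by the glucose transporter Slc2a1 at -0.42 ± 0.31 (SD, n = 10) and the enzymes Pgam1 at -0.32 ± 0.23 (n = 11) and Tpi1 at -0.27 ± 0.27 (n = 11), while the aldolase Aldoa was higher at 0.30 ± 0.16 (n = 11). The mean of the list was -0.20, and without centring it was 0.06, though still low against other genes. On the 18 arrays 6 members fell and 1 rose (7 and 1 adjusted over the list alone), with Pfkl at -0.81, the glyceraldehyde phosphate dehydrogenase Gapdh at -0.52 ± 0.48 (n = 11), Slc2a1 at -0.41 ± 0.31 (n = 10), Pgam1 at -0.40 ± 0.29 (n = 11) and lactate dehydrogenase Ldha at -0.23 ± 0.14 (n = 11). The list mean was -0.29 there and lay below 0 at all 11 time points, from -0.01 at time point 1 to -0.79 at time point 10, whose mean rested on 1 array. On all arrays the list mean was 0.04 at time point 6 and -0.27 at time point 10, and it was negative at the other 9 time points. Pfkl (-0.48 ± 0.90, SD, n = 11, limma adjusted p 0.170) and Gapdh (-0.34 ± 0.49, n = 11, adjusted p 0.0827) were not called on all arrays, where Gapdh passed only when adjusted over the list alone.

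Camera gave the glycolysis list an unadjusted p of 0.00498 and an adjusted p of 0.134 on all arrays, and an adjusted p of 0.00695 in the reduced set, where it was the only list called of 24. With an estimated correlation the adjusted p was 0.621 and 0.243, over lists with 5 or more members measured at every time point. On all arrays camera called 0 of 27 lists, with 4 at an unadjusted p under 0.05, and it called 1 list without time point 5 or without time point 6. Fry called 7 of 21 and the exact sign-flip test 12 of 27, but these tests ask only whether a list moved and not whether it moved more than other genes.

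**Figure D3:**
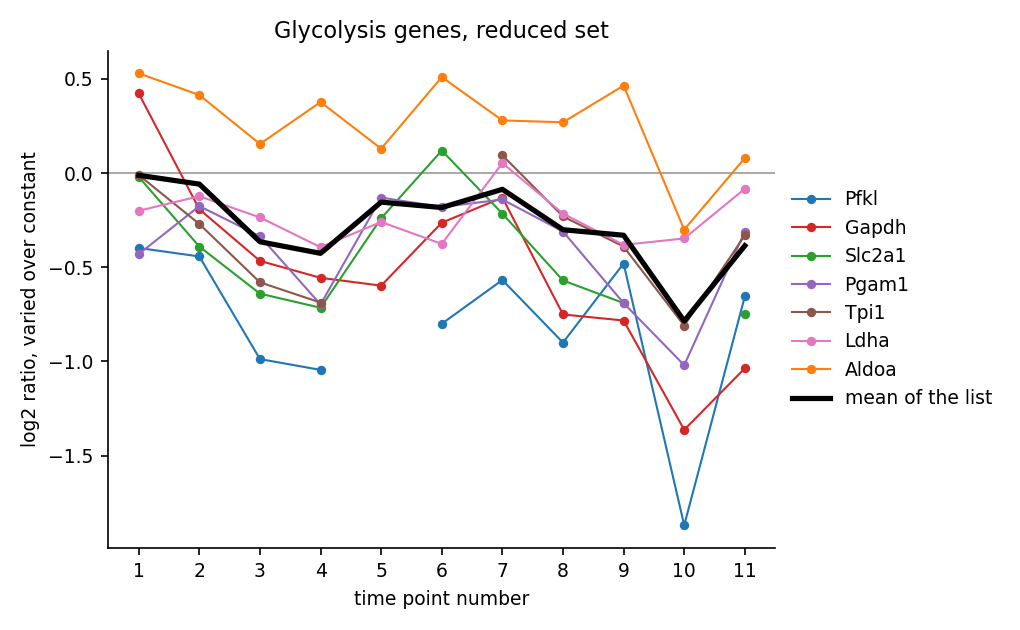
Log2 ratio (y axis) of 7 glycolysis genes at the 11 time points (x axis) in the reduced set, with the mean over the 10 measured members of the list as a thick line; gaps are time points without a value. The list mean lies at -0.01 at time point 1, -0.43 at time point 4, -0.09 at time point 7 and -0.79 at time point 10.

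Other lists of energy metabolism had members on both sides, and their counts refer to all 20 arrays unless stated. In the tricarboxylic acid cycle 2 of 13 measured members were higher, the succinyl-CoA ligase subunit Sucla2 at 0.33 ± 0.14 (SD, n = 11), and malate dehydrogenase Mdh2 at 0.29 ± 0.13 (n = 11). In oxidative phosphorylation 1 of 25 was higher (Cox5b, 0.21) and 2 lower (Cox7b, -0.28, and Cox6a1, -0.20), and none was called adjusted over the list alone. The reduced set had 3 of 20 higher, among them Ndufa5 (0.27) and Cox5b (0.25), and 3 lower (3 and 2 adjusted over the list alone). In fatty acid oxidation 1 of 8 was higher (Acads, 0.21) and 2 lower (Acadvl, -0.31, and Etfa, -0.23), with 1 and 3 adjusted over the list alone. The list mean was negative at all 11 time points (camera adjusted p 0.316, exact sign-flip adjusted p 0.00879). In fatty acid and triglyceride synthesis 1 of 6 was higher, the lipid droplet enzyme Pnpla3 at 0.43 ± 0.20 (n = 11). In the hypoxia response 2 of 7 were lower, and these were the glycolysis genes Slc2a1 and Ldha (list mean -0.17, camera p 0.0192, adjusted p 0.258).

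Of 33 listed genes of the ATF4 response to a lack of amino acids, 10 were measured, and 2 of these were higher and 2 lower. Sesn2, an inhibitor of growth signalling, was at 0.25 ± 0.17 (SD, n = 11) and the stress transcription factor Ddit3 at 0.28 ± 0.32 (n = 11), against -0.64 ± 0.41 (n = 11) for Cebpb and -0.48 ± 0.54 (n = 10) for Jdp2. The limma adjusted p of Ddit3 was 0.0444, and it was positive at 9 time points and negative at 2. Its call was lost when any time point other than 7 or 11 was left out. The mean of the ATF4 list was -0.06 (camera adjusted p 0.844, estimated-correlation adjusted p 0.885, fry adjusted p 0.652, exact sign-flip adjusted p 0.130), which does not decide whether the response took place. Asparagine synthetase (Asns) and glutamine synthetase (Glul) had probes but no value on any array. Slc38a2 had values on 3 arrays, so these 3 genes could not be tested. The glutamine transporter Slc1a5 had values on 11 arrays, too few for the main limit. With 6 or more time points required, it lay at -0.03 ± 0.64 (SD, n = 8, limma adjusted p 0.939) on all arrays. In the reduced set, a test chosen after the data were seen, it lay at -0.31 ± 0.19 (n = 6, limma adjusted p 0.0170), negative at each. Under this requirement the adjusted p of Ddit3 on all arrays was 0.0511. Only 4 of 27 genes of glutamine and glutamate metabolism were measured, of which Gad1 was higher (0.26 ± 0.20, n = 10, adjusted p 0.0171 by limma), with Glud1 at 0.07, Got1 at 0.03 and Psat1 at -0.01.

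None of 7 amino acid transporters passed the test, and Slc38a3 lay at -0.18 ± 0.45 (SD, n = 9) and Slc7a5 at 0.11 ± 0.20 (n = 10). Slc38a3 was negative at 8 time points and 0.95 at time point 10, without which its mean was -0.32 (limma adjusted p 0.00506). Without time point 5 the mean of Slc7a5 was 0.16 (limma adjusted p 0.0388). Among endoplasmic reticulum chaperones 2 of 9 were lower, the disulfide isomerase P4hb at -0.49 ± 0.29 (n = 11) and Edem1 at -0.28 ± 0.26 (n = 10). The co-chaperone Stip1, at 0.27 ± 0.24 (n = 11), was the 1 of 8 heat shock proteins called. The list mean was above 0 at 10 time points (camera adjusted p 0.342, exact sign-flip adjusted p 0.0188). In purine and pyrimidine synthesis 1 of 6 members was lower, Umps at -0.22 ± 0.13 (n = 11), and 2 were adjusted over the list alone. In the glutathione and thioredoxin list Prdx2 was higher (0.19) and Gpx3 lower (-0.47 ± 0.39, n = 11) of 13, with 3 higher and 1 lower adjusted over the list alone. In the list of p53 targets Gadd45b was the 1 of 8 called.

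In cell cycle and DNA replication 6 of 23 measured members were higher and 0 lower, among them the kinase partner Cks1b at 0.38 ± 0.34 (SD, n = 11), Rfc1 at 0.30 ± 0.31, the phosphatase Cdc25c at 0.26 ± 0.18 and Ccnd3 at 0.25 ± 0.29. The list mean of 0.19 was 0.06 over the 17 members of the reduced set, where 5 were higher and 1 lower. Of 42 cytosolic ribosomal proteins 9 were higher and 2 lower, with Rps24 at 0.35 ± 0.25 (n = 11) and Rpl11 at 0.34 ± 0.20 (n = 11) against Rpl39 at -0.37 ± 0.34 (n = 11) and Rps20 at -0.36 ± 0.26 (n = 9). Their camera p was 0.0287 (adjusted p 0.258). Of 42 measured there too, 16 were higher and 2 lower in the reduced set, with Rpl9 at 0.43 ± 0.46 (n = 10) and Rpl13a at 0.37 ± 0.13 (n = 11). Of 19 translation factors 4 were higher and 1 lower (5 and 1 adjusted over the list alone), with Eif4g2 at 0.52, nucleolin Ncl at 0.36, Eif5a at 0.21 and Eif4b at -0.22. Of 15 proteasome and ubiquitin genes 2 were lower, the subunits Psmb2 at -0.54 ± 0.12 (n = 10) and Psmd11 at -0.42 ± 0.36 (n = 11). Of 5 histones and chromatin proteins Hdac2 was higher (0.23), and of 14 lysosome and autophagy genes the protease Ctsl was higher (0.33), with 3 higher and 2 lower adjusted over the list alone.

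Albumin (Alb), the main secreted protein of liver, was lower at -0.56 ± 0.21 (SD, n = 9), and it was negative at each of its 9 time points. Of 12 liver secreted proteins 2 were lower, Alb and Itih3 (-0.29), and 1 higher, the apolipoprotein Apoc3 (0.24). There were 4 lower and 1 higher when adjusted over the list alone. Of 5 hepatocyte markers 1 was lower (2 adjusted over the list alone), and their mean of -0.17 was negative at all 11 time points (camera adjusted p 0.342, exact sign-flip adjusted p 0.00879). In the reduced set it was -0.16 and was positive at time point 5 (0.02). Of 11 genes of extracellular matrix and adhesion the integrins Itgb1 (-0.38 ± 0.15, n = 10) and Itga5 (-0.31) and the cadherin Cdh1 (-0.19) were lower and the collagen Col1a2 was higher (0.19). Col1a2 was also the 1 of 5 markers of stellate cells or fibroblasts called, with 1 more lower adjusted over the list alone.

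Of 19 cytoskeletal genes Tubb2b (0.32) and Capg (0.20) were higher and Krt8 was lower (-0.25), with 1 and 1 adjusted over the list alone. Of 9 interferon genes Oasl2 was lower (-0.27). Of 8 immediate early genes Gadd45b was higher (2 higher and 1 lower adjusted over the list alone). None of 7 acute phase genes was called by limma, where Cxcl1 lay at 1.07 ± 2.61 (SD, n = 11) and Ccl2 at 0.43 ± 0.94 (n = 11). The value of 8.90 at time point 10 set the mean of Cxcl1, which was 0.37 ± 0.33 (n = 11) in the reduced set (limma adjusted p 0.00347). For all lists not singled out, the counts adjusted over the list alone were the same as those over all genes. Camera pointed down although the list mean was above 0 for oxidative phosphorylation, purine and pyrimidine synthesis, glutathione, acute phase and lysosome genes. The median and mean had opposite signs for the ATF4, glutathione, proteasome, liver secreted and lysosome lists.

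Called members in the reduced set, higher and lower, were 3 and 0 for the tricarboxylic acid cycle (2 and 0 adjusted over the list alone), 1 and 3 for fatty acid oxidation (2 and 6), 2 and 0 for fatty acid synthesis and 0 and 2 for hypoxia. They were 2 and 3 for the ATF4 list, 0 and 0 for amino acid transporters, 0 and 2 for endoplasmic reticulum chaperones, 2 and 0 for heat shock proteins, 4 and 1 for glutathione and 2 and 0 for p53 targets. Translation factors had 5 and 1, proteasome genes 1 and 4, lysosome genes 0 and 2, liver secreted proteins 1 and 3 and hepatocyte markers 0 and 2. Acute phase genes had 1 and 1, immediate early genes 2 and 1 (4 and 1 adjusted over the list alone), cytoskeletal genes 3 and 2 (4 and 4), matrix genes 2 and 3 and interferon genes 1 and 2. Purine synthesis, histones and stellate markers had fewer than 5 members there. Of the histone list Hdac2 (0.22) and Hmgb2 (0.26) were called higher, and of purine synthesis Umps (-0.21) and Aprt (-0.20) lower.

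The 12 lists with fewer than 5 measured members on all arrays had no list test. Of their members on all arrays, Gad1 and the macrophage marker Aif1 were higher, and the endothelial marker Kdr (0.35 ± 0.52, SD, n = 11) passed only when adjusted over the list alone. In limma none of the measured aminoacyl-tRNA synthetases (4), gluconeogenesis genes (4), urea cycle genes (4), clock genes (3), cholangiocyte markers (3), cholesterol genes (1), metallothioneins (1) and lymphocyte markers (1) was called, and no erythroid marker was measured. The reduced set differed, with the urea cycle gene Asl (-0.21 ± 0.20, SD, n = 11, limma adjusted p 0.0138) and the cholangiocyte marker Krt19 (-0.26 ± 0.28, n = 9, adjusted p 0.0224) lower. There Kdr was higher at 0.21 ± 0.17 (n = 9, adjusted p 0.0194), and Gad1 and Aif1 were called again. Of 2 macrophage markers measured, Cd163 lay at 0.88 ± 2.77 (SD, n = 9) on all arrays and at -0.08 ± 0.29 in the reduced set. Without centring 9 of the genes named here changed sign, as listed at the end, among them Ldha, Cdh1, Krt8, Etfa and Oasl2. Some genes named above lost their call when 1 or more single time points were left out, namely 1810009A15Rik, Itga4, Csf1, Capg, Ccnd3, Cox5b, Cox6a1, Cox7b, Ddit3, Edem1, Eif4b, Eif5a, Itih3, Jdp2, Prdx2, Rfc1 and Tpi1.

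Differences among time points asked which ratios moved over the 96 h. On all arrays most of the 10 genes with the smallest F-test p took their differences from the arrays that stood apart. Jrk, Arpc5l, Dclk1, Lhx2 and probe 12897 had 16.87 at time point 10, from its second array, and lay between -0.56 and 0.28 at all other time points. As 111 spots of that array share this value, it cannot be read as the size of a change. Ext1, Creg1, Cdh4 and probe 11301 were highest at time point 5, at 2.35 to 2.74, and they have spots at the raised positions, while probe 14700 was lowest at time point 6 (-1.57). The limma F test called 262 of 3744 genes at an adjusted p under 0.05, with adjusted p between 1.30e-10 for Jrk and 0.00109 for probe 11301. The count was 1969 without the first array of time point 10 and 1055 without its second. It was 170 and 174 without the first or second array of time point 7, and 172 and 173 without those of time point 2. On the reduced set it called 1050 of 3962 genes, of which 160 had been called on all arrays. There the adjusted p was 0.712 for Jrk, 0.488 for Arpc5l, 0.390 for Dclk1, 0.140 for Lhx2, 0.664 for Creg1 and 0.602 for Cdh4, against 0.0472 for Ext1, 0.000330 for probe 11301 and 1.68e-11 for probe 14700.

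Among the 18 arrays the strongest differences were low values at time points 6 and 7. Phactr3, a regulator of actin and protein phosphatase, lay at -2.64 at time point 7 and was also low at time point 6, against -0.48 to 0.49 elsewhere. Prg2 (-2.80), the mitochondrial ribosomal proteins Mrpl24 (-2.24) and Mrps10 (-2.23), probe 12059 (-2.47) and the homeobox gene Hoxb4 (-2.13) were lowest at time point 7, and Lypd3 (-1.77), Dzip3 (-1.68) and probe 5111 (-1.58) at time point 6. The limma F test gave adjusted p between 4.65e-25 for Phactr3 and 1.39e-17 for Hoxb4. A set of 16 unnamed probes, at multiples of 60 in blocks 27, 28, 31 and 32 of 540 probe numbers, had a median of -1.21 at time point 7. These places were chosen after the low values were seen. Mtmr9, a myotubularin-related protein, followed another course, with -1.60 at time point 1, -2.51 at time point 4, -1.93 at time point 7 and -0.44 at time point 8 (adjusted p 5.46e-18).

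At single time points, the ratio was tested against 0. The ratio of Nfia was 0.93 ± 0.13 (SE) at time point 1, 0.87 ± 0.13 at time point 4 and 0.89 ± 0.13 at time point 7, each over 2 arrays, and it passed the limma test at each of these. Mtmr9 lay at -1.60 ± 0.29 (SE) and -2.51 ± 0.29 at time points 1 and 4. Map2k6, a kinase of the p38 pathway, was at -1.78 ± 0.25 at time point 4, Pacc1 at -1.24 ± 0.19 at time point 3 and Gpr153 at -1.04 ± 0.19 at time point 1. Ppp2r5e (0.91 ± 0.14) and Ccdc28b (0.93 ± 0.15) were highest at time point 3. Probe 13913 reached 0.80 at time point 1 and 0.88 at time point 4. Zfp51 reached 0.96 ± 0.16 at time point 7, where Phactr3 (-2.64 ± 0.19) and Prg2 (-2.80 ± 0.22, on 1 array) were lowest. At time point 6 the named genes had a value on the first array alone, with Vim at 1.92, Mapt at 1.87, Nxf2 at -2.13 and Lypd3 at -1.85. At time point 10 they had a value on the second array alone, with Arpc5l and Dclk1 at the repeated 16.87 and Septin5 and probe 10094 both at -2.91. Many values of that array are repeated, so neither value is read as the size of a change.

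On all arrays limma called 27 genes higher and 7 lower at time point 1, 6 and 1 at time point 3, 44 and 40 at time point 4, 329 and 70 at time point 5, 75 and 56 at time point 6, 133 and 194 at time point 7, and 228 and 228 at time point 10. None was called at time points 2, 8, 9 and 11, where 411, 430, 515 and 264 genes had an unadjusted p under 0.05 against 187.1, 181.6, 187.05 and 177.6 by chance. Robust variance estimation called 4 lower genes at time point 9 and none at the others. With arrays scaled to equal spread, 90 genes were higher and 19 lower at time point 2, 25 and 14 at 8, 75 and 47 at 9 and 6 and 45 at 11. Without centring the counts were 1116 and 1, 1423 and 3, 582 and 10, and 0 and 0. Of the 329 higher genes at time point 5, 77.8% had a spot at the first 3 of 20 positions, far above the share of all tested genes that lie there. Between 25 and 600 genes were higher and between 59 and 492 lower at a time point of the reduced set, most often at time points 1 (590 and 216), 4 (600 and 354) and 7 (588 and 492). The calls of all time points came to 5604, against 1438 on all arrays, 6238 without the first array of time point 10 and 5060 without its second. Time points 5 and 11, and in the reduced set 6 and 10, had 1 array and were assumed to vary like the others.

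The counts of single time points on all arrays depended on single arrays. Each gene had 1 spread in this fit, pooled over the time points with 2 arrays. The pair of time point 10, whose arrays did not correlate, thus entered the spread used at every time point. Leaving out either of its arrays takes this pair out of the spread. The lack of calls at time points 2, 8, 9 and 11 therefore does not show unchanged ratios. Without the first array of time point 8, limma called none at time points 1, 3 and 4, where 795, 595 and 855 genes had an unadjusted p under 0.05 on all arrays. Without either array of time point 2 it called none at time points 1 and 3 and 3 lower genes at 4. Without any single array of time points 1, 3, 4, 7 and 9 or the second of time point 8, it called at most 5 genes at time point 1 and 4 at time point 3. A block for the arrays titled r also left none at time points 1 and 3 and 9 higher and 9 lower genes at 4, so the calls named above for time points 1 and 3 were lost. Time point 7 had 8 higher and 68 lower genes without its first array and 20 and 89 without its second. Time point 6 had 1 and 0 without its first array and 108 and 90 without its second. Time point 10 had 727 and 817 without its first array, 137 and 149 or 137 and 151 without the first or second array of time point 2, and 131 and 156 without the first of time point 3. Without the first array of time point 10, 502 and 163 genes were called at time point 1, 230 and 138 at 3, 514 and 296 at 4, 519 and 264 at 5, 229 and 243 at 6 and 506 and 431 at 7. The time points without calls on all arrays then had 58 and 33 (2), 96 and 84 (8), 152 and 144 (9) and 12 and 80 (11). Without the second array of time point 10 they had 58 and 34, 94 and 84, 150 and 139, and 12 and 79.

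**Figure D4:**
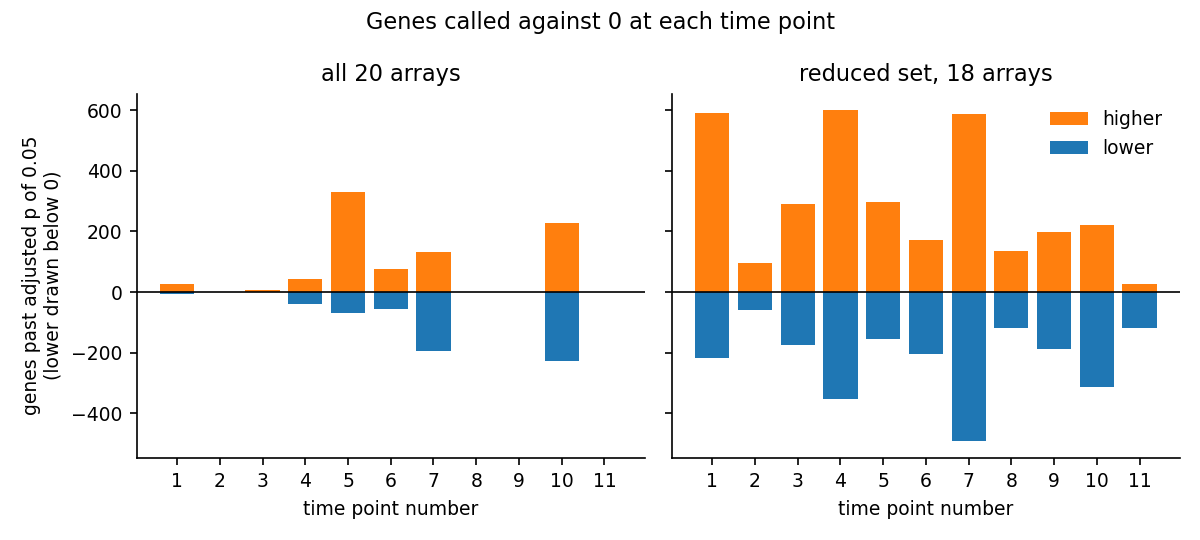
Number of genes past an adjusted p of 0.05 (y axis; higher above 0, lower drawn below) at each time point (x axis), with all 20 arrays on the left and the reduced set of 18 arrays on the right. On all arrays time points 2, 8, 9 and 11 have none; in the reduced set time point 4 has 600 higher and 354 lower genes.

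The reduced set gave a marked course for Hspa5, the main chaperone of the endoplasmic reticulum, which the rule named at time points 4 and 9. Its ratio was 0.20 at time point 1, 0.64 at 2, 0.72 at 3 and 0.98 ± 0.16 (SE, 2 arrays) at 4, then -0.82 at 7, 0.26 at 8, 1.00 ± 0.16 at 9, 1.09 at 10 and -1.35 at 11. Limma gave adjusted p of 1.95e-06 at time point 4, 3.69e-05 at 7, 3.90e-06 at 9, 0.000263 at 10 and 1.61e-05 at 11, and 2.36e-15 for differences among time points. Its probe lies at the raised positions, so time points 5 and 6 were left out. On all arrays Hspa5 was not called at time points 4, 9 and 11, so those calls rest on the reduced set. The 8 measured chaperones of the endoplasmic reticulum, taken over all pairs of members, showed no shared variation. Single members were not compared with Hspa5, so this does not show whether any of them shared its course. Their mean correlation over time points was -0.0593, against 0.0110 in random lists (permutation test with random lists, p = 0.815). At other samplings the rule named Hoga1 (1.04 ± 0.14, SE) and Gtpbp6 (-1.17, 1 array) at time point 1, S100b (0.77) and Klhl10 (-0.90, 1 array) at time point 2, and probe 9434 (0.97) at time point 4. At time point 8 it named probes 14399 (1.13) and 12940 (0.80), the guidance protein Sema6a (-1.07, 1 array) and 3000002C10Rik (-1.03 ± 0.14), and at time point 9 Zfp934 (0.86), Notch3 (-1.31 ± 0.14) and Pacc1 (-1.23 ± 0.15). All of these passed the limma test in the reduced set.

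A periodic component asked whether ratios followed the repeated removal and return of glutamine, under the assumption that 5 steps make a full cycle. The smallest p belonged to probe 12940, with an amplitude of 0.46, and to 4930480K23Rik (0.66), Lysmd2 (0.59), Stmn4 (0.45) and Caml (0.38), but each had an adjusted p of 0.864 in limma. No gene of 4752 was called, and 178 had an unadjusted p under 0.05 against 237.6 by chance. Robust variance estimation also called none. In the reduced set, with 243 genes at an unadjusted p under 0.05 against 212.55 by chance, the lowest adjusted p was 0.304, for Nmrk2, a kinase of NAD synthesis (amplitude 0.56), and 4930480K23Rik (0.67). They were followed by 1700020L24Rik (0.56), Dusp26 (0.54) and Csdc2 (0.39). No period of 4, 5.5, 6 or 6.5 steps gave a call either.

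Profiles of neighbouring time points were more alike than others, so p-values that treat time points as independent may be too small. The mean correlation across 4752 genes was 0.396 for 10 neighbouring pairs and 0.273 for 45 other pairs (one-sided permutation test over the order of time points, p = 0.00669). Arrays of 1 time point had a mean correlation of 0.458 over 9 pairs, against 0.282 over 181 pairs of different time points (permutation p = 0.000200). For the reduced set these values were 0.485 and 0.363 (permutation p = 0.00200), and 0.584 and 0.362 over 7 and 146 pairs (permutation p = 1e-05, the smallest that 100000 permutations can give). The lowest correlation between any 2 arrays was -0.0667, for the second array of time point 10.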

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

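Of the tests below, all those that weigh an explanation were chosen after the result was seen. The F test among time points was fixed earlier.

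The ratio of 262 genes differed among time points on all 20 arrays. The limma F test gave the smallest adjusted p for Jrk (1.30e-10), probe 12897 (2.90e-10), Arpc5l (5.13e-10), Dclk1 (2.33e-09) and Lhx2 (8.02e-08). These had 16.87 on the second array of time point 10, a value that 111 of its spots share. They were followed by Cdh4 (0.000696), Ext1 (0.000779), probe 14700 (0.000887), Creg1 (0.000887) and probe 11301 (0.00109).

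The second arrays of time points 6 and 10 stood apart from the other arrays but correlated with each other at 0.397. The explanations below were tested for each array alone, and none was tested against this value. At time point 6 the spots with a value correlated at 0.00704 with those of the other arrays, which values deposited in another order of probes would give. Other transcript levels in the cells were argued against by the ribosomal protein probes, of which 33.3% had a value, against 61.4% to 89.5% on the other arrays. At time point 10 the same correlation was 0.830, which argues against another order. Ratios of small whole numbers may explain its repeated values other than 16.92 (111 spots), which is too large for such a ratio. Of its values, 16.5% lay on the 3 most frequent ones. The other arrays reached up to 6.39%, above the limit of 4% set for them, so this stayed open.

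Values at time points 5 and 6 were raised at the first positions of every 20 probe numbers. On the array of time point 5 the first position had a median 2.87 above the last 10 positions, so the place on the print is a candidate explanation. Higher transcript levels as the whole cause were argued against, because 77.8% of the 329 genes called higher there by limma lay at the first 3 positions.

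Genes such as Phactr3, Prg2 and the mitochondrial ribosomal proteins Mrpl24 and Mrps10 had low values at time points 6 and 7. Of 52 probes that fell on both arrays of time point 7 and had no low mean at time points 1 to 4, 8, 9 and 11, 40 had a gene name, and no fixed list held 2 of them. The lists could not show a relation among mitochondrial ribosomal proteins, since none covered these. Signal that does not come from the named gene may explain the fall, but the test could not decide this. It took 16 unnamed probes at multiples of 60 in blocks 27, 28, 31 and 32, with a median of -1.21 at time point 7. These places were chosen after the fall was seen, so low values there are no independent evidence. Fewer transcripts stayed open, because only 2 of the genes, Zfp618 (-0.25) and Trmt11 (0.21), had other probes with a value, with a mean of -0.0175.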

How the results depend on the processing

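Settings on the reduced set, on blocks, on the 2 arrays left out, on time points 5 and 6 and on a period of 6.5 steps were chosen after the results were seen. The cause was not tested for any change below unless stated.

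Without centring, the mean difference had 2895 calls (2849 higher and 46 lower) and single time points 10929. Camera called 1 list, glycolysis, whose mean was then 0.0571. The means of 9 genes changed sign: Slc38a3 0.0789, Cox6a1 0.0523, Etfa 0.0177, Umps 0.0336, Eif4b 0.0323, Krt8 0.0215, Cdh1 0.07, Ldha 0.0465 and Oasl2 0.0144. With arrays scaled to equal spread, 823 genes were higher and 541 lower.

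With genes measured on every array, of which 596 were tested among time points, 221 genes had a mean difference (187 higher and 34 lower), 60 differed among time points and 353 calls came from single time points. Genes with a value at 6 or more time points gave 597 higher and 605 lower. With each probe on its own, camera called 3 lists, and with fry 7 lists were called. At an adjusted p under 0.10, 403 genes differed among time points.

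With the sign of the arrays titled r turned, 0 genes had a mean difference in limma, 5 differed among time points, and single time points had 177 calls. Camera called 2 lists. The gap between neighbouring and other time points was 0.0212 (permutation p = 0.255) and that of arrays of 1 time point -0.473. Slc7a5 was then at -0.0128, Edem1 at 0.038, Aldoa at -0.00386 and Cxcl1 at -0.576. At time point 1 Nfia was at -0.04, Mtmr9 at 0.16 and Gpr153 at 0.12, and at time point 3 Ppp2r5e at -0.18. At time point 4 probe 13913 was at -0.1775, Nfia at -0.1275 and Mtmr9 at 0.1775. At time point 7 Zfp51 was at -0.17, Prg2 at 2.8 and Phactr3 at 0.305, and at time point 10 Arpc5l and Dclk1 at -16.87 and probe 10094 and Septin5 at 2.91. This setting served to test the direction of these arrays.

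Only the arrays titled without r gave 1 called list, and only those with r gave 315 mean differences (242 higher and 73 lower), with Ccl2 at -0.0271. Array numbers did not pair across time points, with 36 correlations of their differences between -0.432 and 0.332. With all 20 arrays as separate replicates, 1316 of 3744 genes had a mean difference (933 higher and 383 lower), and adding a block for the arrays titled r lowered this to 1281 (910 higher and 371 lower). With the block, 188 genes differed among time points and 1144 calls came from single time points.

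With 1 time point or array left out, mean differences ranged from 806 (time point 4) to 1326 (time point 10). Lists ranged from 0 to 1, with 1 called by camera without time point 5 or 6. Differences among time points ranged from 170, without the first array of time point 7, to 1969, without the first array of time point 10. Single time points ranged from 1002 to 6238, the highest again without the first array of time point 10. Without its second array the counts were 1055 and 5060.

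Without the second arrays of time points 6 and 10, 1366 genes differed among time points, single time points had 6298 calls and camera called 1 list. The reduced set gave 1050, 5604 and 1. Centred within blocks it gave 1654 mean differences (1072 higher and 582 lower), 882 genes that differed among time points, 6904 calls at single time points and 1 list, with Cdh1 at 0.0855. Without time points 5 and 6 and the second array of time point 10 these counts were 1849 (1030 higher and 819 lower), 818, 4893 and 1. No setting gave a call of the periodic fit in limma, where 178 genes had an unadjusted p under 0.05 on all arrays.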

Other observations

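Of the tests below, the comparison with lists matched on detection was written down earlier. The tests on random lists, medium changes and ribosomal proteins, and the limits of 2 tests named below, were chosen after results were seen.

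Members of the glycolysis list varied together over the time points of the reduced set, with a mean correlation of 0.383 over 10 genes. In a permutation test none of 10000 random lists reached it (p = 0.000100, the smallest that 10000 random lists can give, adjusted p 0.00120). The same smallest p was found for 42 ribosomal proteins at 0.186. A shared course of glycolysis transcripts is a hypothesis that may explain this. A dye bias of bright spots that differs between arrays was not excluded by lists matched on detection (p = 0.000200), because matching moved the random mean correlation only from 0.0109 to 0.0194. That reason, which overrides the limit written down earlier, was found after the value was seen. Gapdh, Pfkl, Pgam1, Pgk1, Tpi1 and Aldoa were lowest at time point 10, and Ldha, Pklr and Slc16a3 were not. Time point 10 rested on 1 array in the reduced set (list mean -0.79). The mean correlation was not recomputed without it.

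A bias shared by bright spots was also tested on ribosomal proteins, which are abundant too. Their mean course correlated with that of glycolysis at 0.422 over 11 time points (one-sided permutation test, p = 0.0845, one-sided upper bound 0.775), so such a bias stayed open. Ribosomal proteins lay 0.370 ± 0.199 (SD) above glycolysis and higher at 11 of 11 time points, but a constant distance does not bear on shared variation. A course that follows the medium changes stayed open, since a wave of 5 steps had a permutation p of 0.145 for the glycolysis list, and the limit for excluding it was changed after this value was known. A wave of 6 steps gave a permutation p of 0.0102 for glycolysis (adjusted p 0.121) and of 0.00270 for the hypoxia list (adjusted p 0.0648), so no list passed the adjustment.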
